A study of Homo sapiens with 9 samples.

How the data were processed

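Reads of sgRNAs in genomic DNA were counted in 9 libraries of a Cas9-expressing OCI-AML2 clone, 1 at day 0 and 2 at day 21 for each of DMSO, palbociclib, venetoclax and the combination. The deposited values are raw counts per sgRNA, 1 column per library. Adapter trimming with cutadapt is named in the submitters' processing notes, with no version, and the aligner or counter, the mismatches allowed and the genome build are not given in the sources used here. Positions and exon numbers are those in the sgRNA names. Where an sgRNA's symbol is a current RefSeq symbol, 10.3% of positions fell inside the gene's bounds in GRCh38.p14, so no position was converted. Of 18009 symbols, 16691 are current RefSeq symbols.

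Libraries held 58694377 to 73321962 reads. The widest 95% Wilson interval of a reported share of reads was ± 0.0124 percentage points. Such intervals cover counting error only, since reads of PCR products without molecular identifiers are not independent molecules. The labels do not state where the replicates separate, so the spread between samples that enters the test of each sgRNA could be technical. A gene's p-value from rank aggregation measures how alike its sgRNAs rank within the same libraries, and does not measure agreement between replicates.

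The 85376 sgRNAs with a mean of at least 30 counts over the 9 libraries were kept, and 17427 genes with at least 3 of them were tested. In R 4.3.3, edgeR 4.0.16 (TMM scaling, robust quasi-likelihood, 5 group means in 1 fit of all 9 libraries) tested each sgRNA. Signed test values were ranked, and robust rank aggregation with a truncation of 0.25 gave an exact 1-sided p per gene and direction. Benjamini-Hochberg adjustment was made per direction with a threshold of 0.05. A gene's log2 fold change is the median over its sgRNAs of differences in group means of log2 CPM (TMM-scaled) with a prior count of 10. Lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01 and again with the correlation estimated. There were 8 comparisons, with 32 lists in each. As a description, list medians were set beside 10000 random lists matched on the change in DMSO since day 0.

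The comparisons, tests, lists, first alternatives and rule for named genes were fixed before the data were examined. The rule takes, against DMSO and against day 0, the 10 genes per direction with the smallest p among those past the threshold with the same sign in both replicates, or the 5 with the smallest p, said not to pass, where fewer than 5 pass. Other comparisons take 5 per direction by the same rule. BCL2, CDK4, CDK6, MCL1, BAX and RB1 are always named in the 3 comparisons of drug groups with DMSO. The first alternatives were no filter, a minimum mean count of 100, scaling by library totals, the replicate number as a block, only the groups compared, counts summed per gene, limma on gene means, DESeq2 1.42.0 and leaving out each replicate. Subtraction of reads shared between libraries, removal of the abundance trend, and gene sums with only the groups compared were added after seeing the data.

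The test was run on simulated data with 50 genes changed per direction and size. Negative binomial counts were unlike the venetoclax libraries (Gini index 0.689 against 0.987 observed), so observed counts were also shuffled among sgRNAs of like DMSO abundance (Gini index 0.986). In the shuffled data 32-fold enrichment was recovered for 38% of genes under venetoclax, 100% under palbociclib and 20% under the combination, and 32-fold depletion for 76%, 94% and 36%. Enrichment of 4-fold was recovered for 2%, 22% and 0%, and depletion of 4-fold for 12%, 26% and 4%. Simulated depletion also thinned reads shared between libraries, which a real loss would leave, so its recovery may be overstated. With no gene changed, 10 shuffles called a mean of 1.4 genes enriched under venetoclax, 27.5 under palbociclib and 1.2 under the combination. The negative binomial data gave 0, 0.2 and 0.1. The 561 genes with 1 or 2 sgRNAs kept were left out of the gene tests.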

Results

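The screen asked which gene knockouts change in abundance when OCI-AML2 cells, an established human acute myeloid leukaemia line, grow under venetoclax, palbociclib or both. Venetoclax inhibits the survival protein BCL2, and palbociclib inhibits the cell cycle kinases CDK4 and CDK6. A Cas9-expressing clone carried a genome-wide pool of single guide RNAs (sgRNAs), and the reads of each sgRNA in genomic DNA were counted. The file held 90709 sgRNAs for 18009 gene symbols. There was 1 library at day 0, and at day 21 there were 2 libraries each for DMSO, the solvent, 1 µM palbociclib, 200 nM venetoclax, and the drugs together at those doses. Depth was 62214242 reads at day 0, 61396142 and 65624685 for DMSO, 60835448 and 72697592 for palbociclib, 73321962 and 62453506 for venetoclax, and 68246043 and 58694377 for the combination.

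Few knockouts held most reads under venetoclax and in 1 of the 2 combination libraries. The median count per sgRNA was 638 at day 0, 558 and 598 in DMSO, and 427 and 512 under palbociclib, against 8 and 6 under venetoclax and 9 and 6 under the combination. The 10 most abundant sgRNAs took 0.356% and 0.345% of reads in DMSO, 2.21% and 2.24% under palbociclib, 67.6% and 61.1% under venetoclax, and 16.97% and 55.1% under the combination. Replicates correlated across sgRNAs, which are not independent replicates, with Pearson r of 0.926 for DMSO, 0.634 for palbociclib, 0.488 for venetoclax and 0.461 for the combination. Fold changes below are log2 medians over a gene's sgRNAs with the SD over those sgRNAs, from groups of 2 libraries, except day 0 with 1. They rest on TMM scaling, and with library totals instead the median of all genes moved by −4.26 under venetoclax and −3.50 under the combination. Adjusted p-values come from edgeR's quasi-likelihood test per sgRNA, rank aggregation per gene and Benjamini-Hochberg adjustment over 17427 genes. With counts summed per gene in place of rank aggregation, edgeR called 0 genes in each of the 8 comparisons, where the dispersion pooled over the 9 libraries was 0.571.

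The comparison of DMSO at day 21 with day 0 shows which knockouts were lost or gained without drug. Genes of basic cell functions were depleted, among them the proteasome chaperone PSMG4 (−4.90 ± 0.72, adjusted p = 8.3e-06), the glycolytic enzyme GAPDH (−4.53 ± 0.42, adjusted p = 1.6e-05), the mitochondrial ribosome protein MRPL21 (−3.88 ± 0.76), the splicing factors PRPF19 (−4.77 ± 1.57) and SNRPD3 (−4.70 ± 0.65), and separase, ESPL1 (−4.83 ± 0.95). ARFRP1, TPI1, FDXR and AARS completed the 10 depleted genes named by rule, with −3.35, −3.78, −3.94 and −4.22. Knockouts of HIF1A, a transcription factor of the response to low oxygen, were enriched (4.49 ± 1.42, adjusted p = 3.0e-07), as were those of ZNF395 (2.37 ± 0.77), NDRG1 (2.07 ± 0.61), RBM12 (2.47 ± 0.59) and BCL11A (1.97 ± 0.64). HSF2, G3BP1, SLC35A1 and DDIT4 were enriched by 1.36, 1.87, 2.01 and 1.57. In all, 1058 genes were depleted and 13 enriched, where the single day 0 library is assumed to vary like the groups with 2.

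Of the 32 gene lists fixed in advance, 21 moved down and 2 moved up since day 0 by camera, and 19 of these calls held with an estimated correlation. In the cytosolic ribosome 26 of 35 genes were depleted, and 35 when adjusted over the list alone (median −3.89, camera adjusted p = 3.8e-62, and 0.0020 with an estimated correlation). DNA replication genes had 26 of 37 depleted, 35 adjusted over the list alone (median −3.15), and the spliceosome 30 of 44, 39 adjusted over the list alone (median −2.91). The mitochondrial ribosome had 37 of 73 depleted, 59 adjusted over the list alone (median −1.86). Genes with tissue-restricted expression outside blood, a reference list of 92, were 1 of the 2 lists moved up, with a median of 0.22 (camera adjusted p = 0.0084, and 0.032 with an estimated correlation) and 0 called by edgeR over all genes and 0 adjusted over the list alone. The calls lost were MCL1 turnover (adjusted p = 0.14 with an estimated correlation), RAS-MAPK inhibition (0.14), the integrated stress response (0.12) and haematopoietic transcription factors (0.25). Raising the minimum mean count to 100 gave 543 depleted genes, and G3BP1 and SLC35A1 lost their calls without DMSO replicate 2 (adjusted p = 0.081 and 0.057).

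Venetoclax against DMSO shows which knockouts were more or less abundant under the BCL2 inhibitor than in DMSO. BAX, which forms pores in the outer mitochondrial membrane during apoptosis, rose in each of its 5 sgRNAs (13.84 ± 0.18, adjusted p = 4.3e-13, and 17.04 with adjusted p = 2.4e-10 when reads shared between libraries were subtracted). BAX sgRNAs held 49.5% ± 2.67 of reads under venetoclax (SD, n = 2), against 0.142% ± 0.00674 in DMSO and 0.137% in the day 0 library. The other named genes were the Mediator subunit MED23 (6.48 ± 4.06, adjusted p = 0.00058), the RNA methylation factor RBM15 (6.50 ± 1.47), the Polycomb cofactor AEBP2 (6.26 ± 2.12), MOCS3 and CTU2 of the pathway that thiolates the wobble uridine of tRNA (6.08 ± 1.88 and 5.36 ± 2.37), the hypusine-forming enzyme DOHH (4.85 ± 2.81), the tyrosine phosphatase PTPN7 (7.04 ± 3.74), BCKDHB (4.95 ± 2.21) and CTDSPL2 (4.47 ± 0.93). As shares of all reads, sgRNAs of MED23 together went from 0.00039% and 0.00086% in DMSO to 0.0014% and 0.0012%, those of PTPN7 from 0.0047% and 0.0043% to 0.0101% and 0.0078%, and those of CTDSPL2 from 0.00093% and 0.00094% to 0.00043% and 0.0020%. Altogether 21 genes were enriched and 0 depleted by edgeR, with 1028 and 960 at an unadjusted p under 0.05, and DESeq2 gave 20 and 0. Of the 21, 6 lay in the lowest 5% of DMSO abundance, MED23 and CTDSPL2 among them, where 10 shuffles of observed counts among sgRNAs of like abundance called 0 to 5, and 15 lay elsewhere, where the shuffles called 0 to 1. The 5 BAX sgRNAs lie on chromosome 19, 4 of them in exon 3 between 49459469 and 49459567 and 1 in exon 4 from 49464068 to 49464091, as the sgRNA names give them, with the genome build not given in the sources used here.

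The drug's target BCL2 had 2.77 ± 5.41 over 3 sgRNAs (adjusted p = 0.51) and MCL1, a related survival protein, −1.93 ± 1.08 (adjusted p = 0.92). CDK6 had 1.87, CDK4 −1.15 and RB1 0.35, none called, and RB1 had −2.86 when shared reads were subtracted. MZF1, MYO18B, NFKBIA, SELM and DAAM1 had the smallest depletion p-values, and these genes did not pass (adjusted p from 0.30 to 0.31). Camera moved 14 lists up and 0 down, led by the spliceosome (median 0.53, adjusted p = 0.00013, and 0.17 with an estimated correlation), and none of these calls held with an estimated correlation. In mitochondrial apoptosis 1 of 18 genes, BAX, was enriched, and 3 were adjusted over the list alone (camera adjusted p = 0.0082, and 0.21 with an estimated correlation). Without venetoclax replicate 2 the enriched count was 3 and 8 of the 10 named genes lost their call (adjusted p from 0.065 to 0.71), BAX and MED23 keeping theirs, and without venetoclax replicate 1 the count was 10 and BCKDHB, DOHH and PTPN7 lost theirs, as PTPN7 did without either DMSO replicate. In each library the sgRNAs that dominated other libraries had reads that tracked those reads, with a fitted share of 0.107% to 0.179% per library. Values high against an sgRNA's reads in the other libraries were left out of the fit. Among those used, single sgRNAs departed from the fitted share, up to 0.932% for RB1 in palbociclib 2, 0.842% for ASPH in venetoclax 1 and 0.850% for ATXN7L3 in combination 2. ASPH and ATXN7L3 were among the most abundant sgRNAs of the other replicate. Subtraction used 1 share per library, so reads above it were left. Shares fitted without BAX came to 85318 and 92565 reads in the DMSO libraries, where 89805 and 89731 BAX reads were counted.

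**Figure D1:**
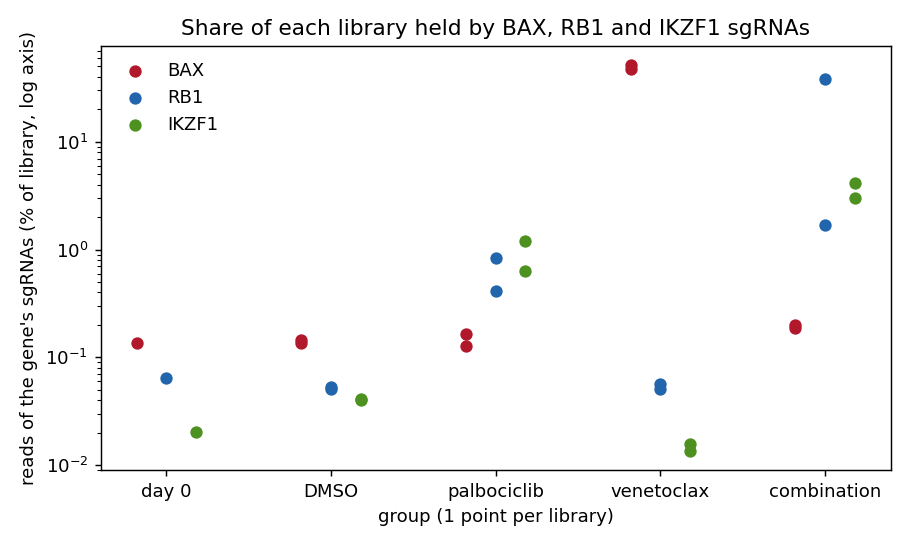
Reads of all sgRNAs of BAX, RB1 and IKZF1 as a percent of each library, on a log axis, with 1 point per library in the 5 groups. BAX holds 49.5% on average under venetoclax and 0.193% under the combination, RB1 reaches 38.1% in 1 combination library, and IKZF1 averages 3.58% under the combination.

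Palbociclib against DMSO shows which knockouts were more or less abundant under the CDK4 and CDK6 inhibitor than in DMSO. AMBRA1, which targets D-type cyclins for degradation, rose in each of 5 sgRNAs (5.97 ± 1.27, adjusted p = 7.5e-05). Further enriched genes were the Ran regulator RANBP1 (4.16 ± 2.13, adjusted p = 2.2e-05), the cohesin subunit STAG2 (3.47 ± 0.85, adjusted p = 7.5e-05), HNRNPU (3.41 ± 0.68), the aryl hydrocarbon receptor AHR (2.99 ± 1.60), the mitochondrial formyltransferase MTFMT (2.73 ± 1.10), the cardiolipin enzyme tafazzin, TAZ (2.64 ± 0.95), the replication licensing factor CDT1 (2.54 ± 1.14), and the folate and purine enzymes MTHFD1 (2.04 ± 1.07) and GART (2.79 ± 1.48). HIF1A was lower than in DMSO (−3.87 ± 1.68, adjusted p = 0.013), as were cyclin E1, CCNE1 (−2.53 ± 0.62, adjusted p = 0.013), UBE2A (−1.95 ± 1.31), ZNF395 (−2.45 ± 1.45), BCLAF1 (−2.82 ± 1.02), ARID4B (−2.93 ± 2.54), the replicative helicase subunit MCM4 (−1.44 ± 0.72) and MDM4 (−1.62 ± 1.57). AARS was also called (−0.70 ± 0.55), although 0 of its 5 sgRNAs fell by more than 1. Its sgRNAs held very few reads, 5.2e-05% and 0.00030% in DMSO and 0.00019% and 5.2e-05% under palbociclib, so these shares overlapped. Knockouts of HIF1A and ZNF395 had also been enriched in DMSO since day 0. Of all reads, HIF1A sgRNAs held 0.00472% at day 0, 0.0986% and 0.0993% in DMSO, and 0.00498% and 0.00575% under palbociclib. Under palbociclib the shares of GART, TAZ, CDT1, MTHFD1 and MTFMT were above DMSO but below day 0. Those of AMBRA1, RANBP1, STAG2, HNRNPU and AHR were above both.

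In total 61 genes were enriched and 11 depleted under palbociclib, against 0 and 0 by limma on gene means, and 110 and 7 with shared reads subtracted. Of the 61, 37 lay among the 871 genes with the lowest abundance in DMSO and 24 elsewhere. When observed counts were shuffled among sgRNAs of like abundance 10 times, 13 to 35 genes were called in the low class and 0 to 4 elsewhere. RANBP1, STAG2, TAZ, MTFMT, CDT1, MTHFD1 and GART belonged to the low class, and AMBRA1, HNRNPU and AHR did not. RB1, the substrate of CDK4 and CDK6 that restrains S phase entry, had 3.03 ± 3.002 (adjusted p = 0.079, then 0.031 with reads shared between libraries subtracted, 0.048 by DESeq2, 0.0066 with only the groups compared, 0.25 to 0.40 without any 1 library and 0.94 by limma on gene means), and its relative RBL2 had 2.98 ± 1.32 (adjusted p = 0.041). Also outside the rule and chosen after their values were seen, CEBPE (4.197 ± 1.05), IKZF1 (4.45 ± 2.02) and KMT2D (3.88 ± 1.77) were enriched. BCL2 had 0.79, CDK4 0.94, CDK6 0.23, MCL1 0.16 and BAX 0.33, none called. Leaving out 1 library changed the enriched count to 106 without DMSO replicate 2 and 33 without palbociclib replicate 2, and the depleted count to 3 without DMSO replicate 1, 1 without palbociclib replicate 1 and 0 without palbociclib replicate 2. Of the 10 named depleted genes, 9 lost their call without palbociclib replicate 1 (adjusted p from 0.23 to 0.41), 10 without palbociclib replicate 2 (0.16 to 0.50), 7 without DMSO replicate 1 and 5 without DMSO replicate 2, and of the named enriched genes TAZ and MTHFD1 did without palbociclib replicate 1.

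**Figure D2:**
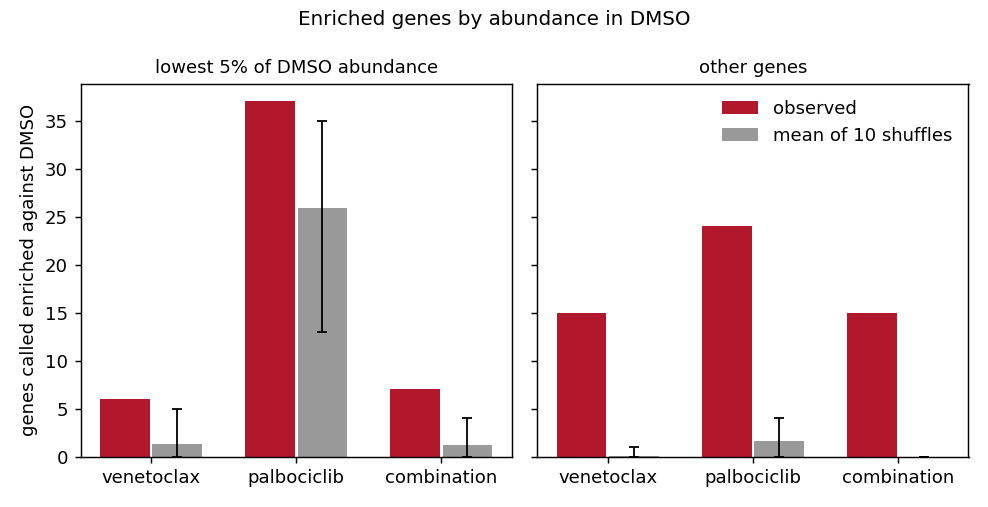
Genes called enriched against DMSO (vertical axis, number of genes) in the lowest 5% of DMSO abundance and among other genes, for each drug group. Grey bars are the mean of 10 shuffles and their whiskers the lowest and highest shuffle, and under palbociclib 37 observed calls stand against up to 35 in the low class and 24 against up to 4 elsewhere.

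Mitochondrial gene expression genes were higher under palbociclib than in DMSO. The mitochondrial ribosome had a median of 0.90 with 66 of 73 genes above 0 (camera adjusted p = 3.2e-24, and 0.0098 with an estimated correlation). MRPS34 (2.27) and MRPS24 (1.66) were called, both in the low class above, and 28 genes were enriched when adjusted over the list alone. Mitochondrial translation factors had a median of 0.87 with 24 of 27 above 0 (7.4e-12, and 0.020 with an estimated correlation), including MTFMT and MTIF2 (1.87), both also in the low class, and 10 adjusted over the list alone. Respiratory complexes III and IV had a median of 0.73 with 0 of 31 called by edgeR and 4 adjusted over the list alone (camera adjusted p = 1.1e-07, and 0.047 with an estimated correlation). The spliceosome had a median of 0.53 with 35 of 44 above 0, 0 called and 12 adjusted over the list alone (2.2e-07, and 0.029 with an estimated correlation), at percentile 89.4 of its matched lists and inside their central 95%. Camera moved 11 lists up and 2 down, and these 4 held.

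The remaining 9 palbociclib list calls, 7 up and 2 down, were lost, and 8 of the 9 are given here. G1 to S inhibitors had 2 of 17 genes enriched, AMBRA1 and RBL2, and 5 adjusted over the list alone (camera adjusted p = 0.0027, and 0.13 with an estimated correlation). The SAGA complex, a chromatin coactivator, had a median of −0.48 with 0 called by edgeR and 3 depleted adjusted over the list alone, TADA2B with the smallest p (−2.33, camera adjusted p = 0.019, and 0.14 with an estimated correlation). Respiratory complex I (p = 0.14 with an estimated correlation), ATP synthase (0.14), mitochondrial shape and cristae (0.14), drug targets (0.14), haem and iron-sulfur genes (0.20) and the cytosolic ribosome (0.27) were likewise lost. G1 to S promoters did not pass (camera adjusted p = 0.18), with 1 of 16 depleted, CCNE1, and 4 adjusted over the list alone.

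**Figure D3:**
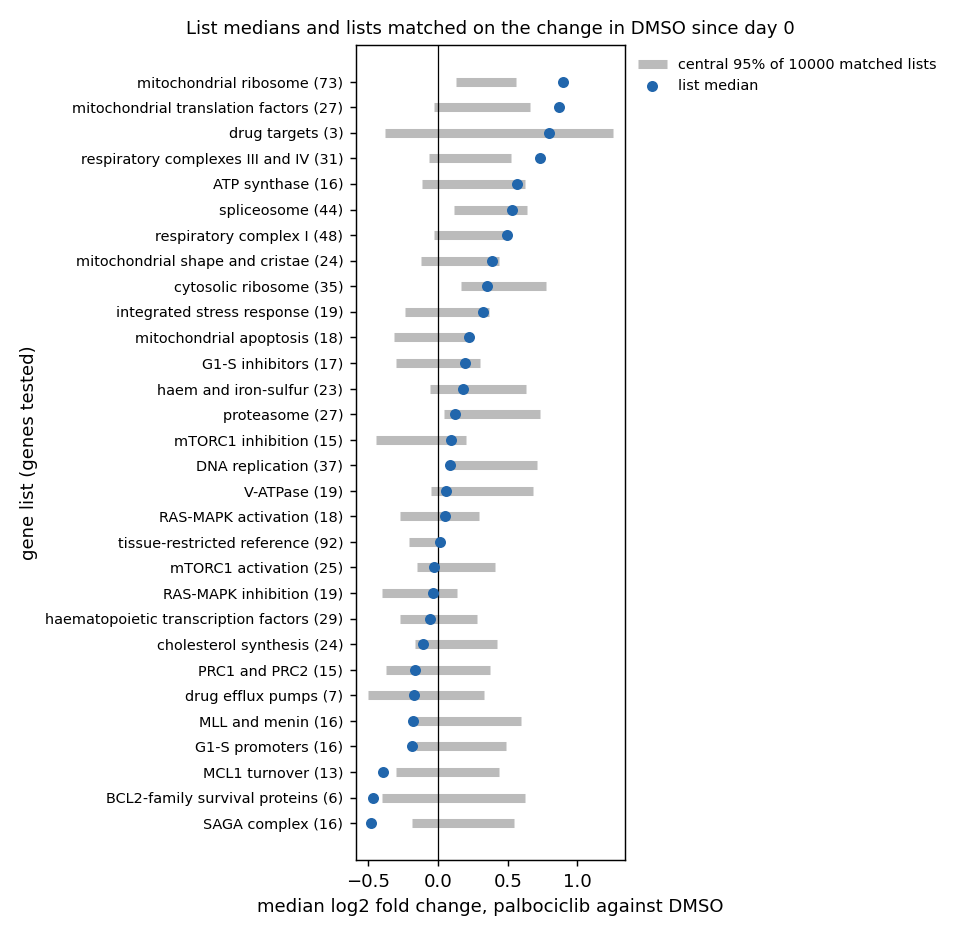
Median log2 fold change of the lists shown under palbociclib against DMSO (points, number of genes tested in brackets) and the central 95% of medians of 10000 random lists matched on the change in DMSO since day 0 (bars). The mitochondrial ribosome at 0.90 lies above its range of 0.13 to 0.56, and the SAGA complex at −0.48 below its range of −0.19 to 0.54.

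The combination against DMSO shows which knockouts were more or less abundant under both drugs than in DMSO. The splicing regulator SRSF10 (9.22 ± 5.41, adjusted p = 4.1e-06), the lymphoid and myeloid transcription factor IKZF1 (11.41 ± 2.81, adjusted p = 0.00011), the RNA-binding proteins HNRNPU (11.37 ± 5.27, adjusted p = 0.00011) and HNRNPH1 (6.48 ± 3.96), TAZ (4.03 ± 2.51), the chaperone adaptor STIP1 (7.29 ± 3.60), the SAGA deubiquitinase subunit ATXN7L3 (7.71 ± 4.70), WRAP53 (6.08 ± 1.01), FAM178A (4.09 ± 2.45) and NFATC2IP (5.59 ± 3.76) were enriched. BAX was also enriched (5.06 ± 0.39, adjusted p = 0.027), at 0.193% ± 0.0109 of reads (SD, n = 2). For BAX, shares fitted without it came to 75.6% and 83.8% of its reads in the combination libraries. With shared reads subtracted, by shares fitted with the BAX sgRNAs included, it had 1.25 (adjusted p = 0.75). IKZF1 sgRNAs held 3.58% ± 0.786 of reads against 0.0407% ± 0.000681 in DMSO, and RB1 sgRNAs 19.9% ± 25.7, with 38.1% of combination replicate 2 in a single exon 7 sgRNA on chromosome 13 from 48936971 to 48936994. RB1 as a gene had 4.12 ± 5.47 and was not called (adjusted p = 0.72), with −1.07 (0.26) when shared reads were subtracted and 3.80 (0.024) by limma on gene means.

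In all, 22 genes were enriched and 0 depleted by edgeR under the combination, with 974 and 932 at an unadjusted p under 0.05, and DESeq2 gave 18 and 0. Of the 22, 7 lay in the lowest 5% of DMSO abundance, HNRNPH1 and TAZ among them, where 10 shuffles called 0 to 4, and 15 lay elsewhere, where they called 0. ZGPAT, INO80D, ZNF420, PLCB4 and IRS4 had the smallest depletion p-values and did not pass (adjusted p from 0.43 to 0.49). BCL2 had 4.55 ± 2.68 (adjusted p = 0.21), CDK6 1.38, CDK4 −1.03 and MCL1 −0.87, none called. Camera moved 6 lists up and 0 down, led by the spliceosome (median 0.94, 33 of 44 above 0, adjusted p = 1.5e-06, and 0.091 with an estimated correlation), and none held. In the spliceosome 0 genes were called and 4 were adjusted over the list alone. The enriched count was 4 without combination replicate 1 and 9 without combination replicate 2, and 7 and 6 of the 10 named genes lost their call (SRSF10, IKZF1 and HNRNPU kept theirs in both). Without DMSO replicate 1 HNRNPH1, FAM178A and NFATC2IP lost theirs, and without DMSO replicate 2 WRAP53 did as well, while BAX lost its call without DMSO replicate 1 (0.16), DMSO replicate 2 (0.17) or combination replicate 1 (0.11).

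Combination against venetoclax shows what palbociclib changed under venetoclax. BAX knockouts were lower with both drugs in each of 5 sgRNAs (−8.91 ± 0.52, adjusted p = 5.3e-05, and −15.78 with adjusted p = 6.9e-05 when shared reads were subtracted), and BAX was the only gene called, with 0 enriched by edgeR, 954 enriched at an unadjusted p under 0.05, and 12 genes changed by DESeq2. IKZF1 (7.21), SLC9A8, UBA6, SRSF10 and ATXN7L3 had the smallest enrichment p-values and did not pass (adjusted p from 0.18 to 0.20), nor did FHL5, TUBB4B and SYNCRIP among lower genes. CARD6, also among the smallest depletion p-values, did not pass and had a median of 2.37, with 2 of 5 sgRNAs lower by more than 1 and 1 higher. The BAX call was lost without venetoclax replicate 1 (adjusted p = 0.074) and without venetoclax replicate 2 (adjusted p = 0.066), at −9.03 and −9.09, and with only the groups compared (−8.69, adjusted p = 0.088), where 1 other gene was called. The test of the interaction of the 2 drugs also called BAX alone (−9.24 ± 0.48, adjusted p = 9.4e-05, but −16.575 with adjusted p = 0.62 when shared reads were subtracted). In that test 0 genes were enriched, with 910 at an unadjusted p under 0.05, and DESeq2 changed 1 gene. That call was lost without DMSO replicate 1 (adjusted p = 0.14), DMSO replicate 2 (0.11) or venetoclax replicate 1 (0.054), at −9.29, −9.19 and −9.38. KANSL1, AHR, KBTBD8 and MEF2D, and in the other direction LPP, CLEC2D, WRAP53, SLC9A8 and GLIPR1, did not pass.

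Combination against palbociclib shows what venetoclax changed under palbociclib. SRSF10 (8.85 ± 5.38, adjusted p = 4.4e-05) and WRAP53, a telomerase and Cajal body factor (5.57 ± 1.07, adjusted p = 0.019), were enriched and 0 genes were depleted by edgeR, with 911 depleted at an unadjusted p under 0.05 and 8 genes changed by DESeq2. IKZF1 (6.52 ± 0.90, adjusted p = 0.0502), POLR2L and BAX did not pass, nor did STAG2, UBE2G1, TRAF5, EDF1 and CKAP2 among lower genes. The SAGA complex was the only list called (median 0.97, camera adjusted p = 0.048, and 0.44 with an estimated correlation), with 0 genes called and 3 adjusted over the list alone. Without palbociclib replicate 2 or combination replicate 2 the count was 0, and without combination replicate 1 it was 1. Without palbociclib replicate 1 other genes were called, and SRSF10 and WRAP53 were not (adjusted p = 0.055 and 0.15).

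Venetoclax against palbociclib tests the difference between the drugs. BAX (13.52 ± 0.27, adjusted p = 8.4e-12), SYNCRIP (9.07 ± 4.18, adjusted p = 3.5e-06), AEBP2 (6.71 ± 3.06), RBM15 (7.15 ± 1.53) and CTU2 (6.08 ± 2.35) were the highest-ranked of 25 genes higher under venetoclax. By edgeR 0 genes were lower, with 970 at an unadjusted p under 0.05, and SSMEM1, ARNT, NUP50, CYB5B and RNF40 did not pass. Camera moved 2 lists up and 2 down, and none held. The mitochondrial ribosome was lower under venetoclax (median −0.97, camera adjusted p = 0.00016, and 0.16 with an estimated correlation) and the SAGA complex higher (median 0.94, 0.00033, and 0.16 with an estimated correlation), with respiratory complex I lower (median −0.62, 0.025, and 0.48) and haematopoietic transcription factors higher (median 0.076, 0.025, and 0.48). The count was 12 without palbociclib replicate 1, where CTU2 lost its call, 6 without venetoclax replicate 1, and 4 without venetoclax replicate 2, where of the 5 named genes only BAX was still called.

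Enriched genes were shared between drugs in few cases. Palbociclib and the combination shared 5, CEBPE, GPI, HNRNPU, IKZF1 and TAZ, where independent lists would share 0.0770. Venetoclax and the combination shared 1, BAX (0.0265 if independent), and venetoclax and palbociclib shared 0 (0.0735 if independent). With reads shared between libraries subtracted, by shares fitted with BAX included, BAX was no longer called in the combination. Fold changes against the same DMSO libraries correlated across genes with Pearson r of 0.238 for venetoclax and palbociclib, 0.273 for venetoclax and the combination, and 0.278 for palbociclib and the combination, against 0.0529, 0.0458 and 0.0538 in negative binomial simulations with no effect. The covariances were 0.145, 0.359 and 0.222, against 0.0195, 0.0303 and 0.0226. In shuffled counts, a comparison added after the results were seen, r was 0.0679, 0.0553 and 0.0422, and palbociclib and the combination shared up to 2 enriched genes and each other pair up to 1.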

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

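All tests of explanations in this part were chosen after the results were seen, while the test of the interaction was planned.

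BAX differed between drug settings in the test of the interaction. Its log2 fold change of −9.24 is the change with both drugs less the sum of the changes with each drug (adjusted p = 9.4e-05, edgeR and rank aggregation). Each of 5 sgRNAs had this direction. PMAIP1, a BH3-only gene with 2 sgRNAs and so outside the gene tests, had a median log2 fold change of 12.33 under venetoclax, with 309513 and 352620 reads against 2468 and 2852 in DMSO. The 12.33 and the rule below rest on TMM scaling, with factors of 5.22 and 5.24 in DMSO and 0.0995 and 0.105 under venetoclax. On that scale an sgRNA with an unchanged share of reads would also rise, so a rise past 5 need not be a gain in share. As shares of reads, PMAIP1 went from 0.00402% and 0.00435% in DMSO to 0.422% and 0.565% under venetoclax. Among 363 genes with 2 sgRNAs, PMAIP1 was the only 1 in which each sgRNA rose by more than 5 in both replicates. That rule was set after values were seen, and no gene-level test was run.

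BAX and other sgRNAs that dominated venetoclax or combination libraries also had reads in every other library. Values that were high against an sgRNA's reads in the other libraries were left out beforehand. Of the 172 values kept, 84.9% lay within 1.5 times their library's median share, as reads assigned to the wrong library could give. The values furthest above the share had been left out, so this percent does not cover them. The SD of log2 of the day 0 share over these sgRNAs was 0.342, against 1.04 for day 0 counts of all sgRNAs kept. This cannot decide whether abundance already present at day 0 played a part. If sgRNAs abundant at day 0 had grown by a like factor, their share would be near constant too. For BAX in the combination, shares fitted without BAX gave at least 75.6% of its reads in both libraries, so its enrichment there may come from reads assigned to the wrong library. Subtraction took it from 5.06 (adjusted p = 0.027) to 1.25 (adjusted p = 0.75). The shares subtracted were fitted with the BAX sgRNAs included, so the loss of the call is partly built in. Subtraction moved the interaction to −16.575 (adjusted p = 0.62), larger in size but no longer called, and the reason was not tested.

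Genes low in DMSO made up much of the palbociclib enrichment. In the lowest 5% of DMSO abundance 37 genes were called, and shuffles that keep only the abundance trend gave up to 35, so a shared upward shift of low genes could account for most of these calls. After subtraction 94.6% of these calls were left. Because subtraction also raised all enriched calls under palbociclib from 61 to 110, this is only weak evidence against reads assigned to the wrong library. Outside that class 24 genes were called against at most 4 in the shuffles, more than the trend gives. What stays open is which low genes rose on their own account.

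The mitochondrial ribosome list was higher under palbociclib than in DMSO, and its genes were also depleted in DMSO since day 0. Its median of 0.90 was at percentile 100 of 10000 lists matched on that depletion, so a shift shared by all depleted genes, as slower division acting alike on them would give, is argued against as the whole source. A part played by slower division, which the design leaves confounded with the drug, stays open, and no other biological explanation was tested.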

How the results depend on the processing

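Subtraction of reads shared between libraries, removal of the abundance trend, and gene sums with only the groups compared were chosen after seeing the data, and the other settings before. Of 12 counts of called genes, DESeq2 and no filter each left 10 within 1.5 times, and no call reversed. With counts summed per gene, 0 genes were called in each comparison. The pooled dispersion was then 0.571, against 0.0127 in day 0 and DMSO alone, where gene sums called 3206 depleted and 2253 enriched since day 0. With only the compared groups, gene sums gave 11 enriched and 0 depleted under palbociclib, and 0 in the comparisons with venetoclax or the combination. For the settings below the cause was not tested. Limma on gene means gave 0 depleted and 0 enriched under palbociclib, 134 enriched under the combination, 361 changed for combination against venetoclax, 76 for combination against palbociclib, 49 for venetoclax against palbociclib, and 327 depleted and 0 enriched since day 0. DESeq2 gave 12 for combination against venetoclax and 8 for combination against palbociclib. Library totals gave 14 enriched under the combination, 5 for combination against venetoclax and 1 for combination against palbociclib, and moved the median of all genes by −4.26 under venetoclax, −0.29 under palbociclib and −3.50 under the combination. No filter gave 6 depleted under palbociclib and 2 for combination against venetoclax. A minimum mean count of 100 gave 543 depleted since day 0, 4 for combination against palbociclib and 2 for the interaction. Only the groups compared gave 7 depleted under palbociclib, 0 for combination against palbociclib and 31 enriched since day 0. With shared reads subtracted, palbociclib had 7 depleted and 110 enriched, the combination 1 depleted and 12 enriched, combination against venetoclax 5 and the interaction 0. With the abundance trend removed, the combination had 2 depleted and 9 enriched, and palbociclib had 42 enriched.

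The labels do not say that replicate numbers pair samples, and correlations of replicate differences between groups ran from −0.005 to 0.0021. The replicate number as a block gave 4 depleted under palbociclib, 2 for combination against venetoclax and 3 for the interaction.

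Leaving out 1 library at a time, with the lone library left assumed to vary like the other groups, gave ranges of 3 to 29 enriched under venetoclax, 0 to 10 depleted and 33 to 106 enriched under palbociclib, 4 to 26 enriched under the combination, 1 to 3 for combination against venetoclax, 0 to 3 for combination against palbociclib, 0 to 2 for the interaction, 4 to 19 for venetoclax against palbociclib, and 946 to 966 depleted and 10 to 11 enriched since day 0. Of 130 named results, 119 kept their side of the threshold with DESeq2, 118 with shared reads subtracted and 107 with only the groups compared. By limma on gene means 85 did, with gene sums 60, and with gene sums and only the groups compared 82. Of 256 list results, most of which were not called, 218 kept theirs with an estimated correlation, and the other 38 were calls that were lost. With library totals 196 kept theirs, 57 calls were gained and 3 were lost. Total reads were alike between groups, but the median count per sgRNA was 6 to 9 under venetoclax and the combination. In shuffled counts 32-fold depletion was recovered for 76% and 36% of genes there and 4-fold depletion for 12% and 4%, so most 4-fold losses would go undetected. These simulated losses also thinned reads shared between libraries, which a real loss would leave, so recovery may be overstated. With shared reads subtracted, the median count of the sgRNAs kept went from 9 and 7 to 1 and 1 under venetoclax. Under the combination it went from 10 and 7 to 2 and 2. After subtraction 40.3% to 44.6% of sgRNAs kept were at 0 in these libraries. Why 0 genes were called depleted was not tested.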

Other observations

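The list of Elongator and its partners and its camera test were written down before their values were seen, and the matched lists were added after that result. Genes outside the rule are named after their values were seen.

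Besides MOCS3 and CTU2, the genes CTU1 (5.09 ± 2.35, adjusted p = 0.020, edgeR and rank aggregation) and URM1 (4.79 ± 2.69, adjusted p = 0.019) of the tRNA wobble uridine thiolation pathway were enriched under venetoclax, as was DPH3 (4.60 ± 3.13, adjusted p = 0.033), a partner of Elongator and of diphthamide synthesis. The haematopoietic transcription factor MEF2D, in the lowest 5% of DMSO abundance, was enriched too (3.14 ± 3.49, adjusted p = 0.023). Under the combination the BH3-only gene BCL2L11 (3.71 ± 3.57, adjusted p = 0.027), the histone methyltransferase NSD1 (5.46 ± 1.41, adjusted p = 0.039) and the demethylase KDM5B (6.70 ± 2.64, adjusted p = 0.040) were enriched.

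A hypothesis from the thiolation genes is that loss of wobble uridine modification as a whole may give an advantage under venetoclax. The remaining pathway members, Elongator and its partners, met the condition set in advance: camera p = 0.0029 upward (0.048 with an estimated correlation), with a median of 0.49 and 6 of 8 genes above 0. The median was at percentile 92.0 of 10000 matched lists, inside their central 95% of −0.75 to 0.73. By edgeR 0 of the 8 genes were called, with a smallest adjusted p of 0.46. Because the added comparison does not set the list apart, although the planned test did, the hypothesis is left undecided.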
